A study of Mus musculus with 12 samples.

How the data were processed

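RNA from mouse cells was measured on Affymetrix MoGene 1.0 ST arrays, which read each gene with short probes spread over its exons. The 12 arrays fell into 5 groups by their labels: skin fibroblasts of 8-week-old mice (2 arrays), mock-infected skin fibroblasts (3), fibroblasts converted to endothelial cells with 5 transferred factors (induced endothelial cells, 3), primary lung endothelial cells (2) and MS-1, a mouse endothelial line from pancreatic islets (2). The mice carried a Tie2-GFP reporter, and the labels call the replicates biological. Skin fibroblasts and MS-1 were kept in DMEM, and the other 3 groups in the endothelial medium EBM-2, all with 10% serum. From each sample 300 ng of RNA was used. The labels do not name the factors; Foxo1, Etv2, Klf2, Tal1 and Lmo2 were taken as the presumed factors from general knowledge of this conversion.

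The deposited values were log2 probe set signals, 1 column per array; the authors named GCOS and RMA, and their versions, settings and annotation are not given in the sources used here. The table held 35556 probe sets. The columns' quantiles still differed, with medians from 7.664 to 7.847 and lower quartiles from 6.177 to 6.402, so the whole table was quantile normalized with limma. Annotation was found for 23410 probe sets. Of these, 21789 carried 1 gene symbol and 1621 several. The other 12146 were not listed. Genes with several probe sets (999) were represented by the one with the highest mean over all arrays, which left 19938 genes. Probe sets with several symbols or none entered only the alternative that tested every probe set. Gene names were checked by gene ID against a mouse RefSeq table, which matched 21698 of the 1-symbol probe sets and renamed 0. The arrays give no counts, so precision rests on the number of arrays.

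Differences were fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with all 12 arrays in 1 model and 1 coefficient per group, for 9 comparisons of groups. Each is given as a log2 difference (first group minus second) with its standard error from the model, and p was adjusted over all genes (Benjamini-Hochberg). Genes with an adjusted p below 0.05 are said to have passed, risen or fallen. Of 34 gene lists, 33 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Members were also counted after adjustment over the list alone. The lists were presumed conversion factors, endothelial identity, endothelial transcription factors, arterial and Notch, venous and lymphatic, angiogenic sprouting, lung capillary, fibroblast, contractile and myofibroblast, mesenchymal transition factors, TGF-beta targets, BMP and ALK1 targets, proliferation, p53 and senescence, interferon response, antigen presentation, inflammatory and adhesion, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, pluripotency, early mesoderm, haematopoietic progenitor and erythroid, macrophage and leukocyte, pericyte and smooth muscle, lung epithelium, mesothelium, keratinocyte, melanocyte and Schwann, adipocyte, skeletal muscle, Hox position code, imprinted, and sex-linked (4 measured, not tested).

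Agreement between the conversion and the natural difference was measured between comparisons that share no array. A signature was taken from genes that differed at least 2-fold the same way in lung endothelial cells and in MS-1 against skin fibroblasts. List means per array were compared with an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1. Genes named in the text were the presumed factors, a fixed set of genes (Tek, Cdh5, Pecam1, Kdr, Nos3, Vwf, Col1a1, Col1a2, Thy1, S100a4, Acta2, Pou5f1 and Nanog), the genes with the largest rise and fall among those passed with groups that did not overlap (10 and 10 for the converted cells against mock-infected fibroblasts and against lung endothelial cells, 5 and 5 elsewhere, leaving out predicted genes and receptor or small RNA families), and up to 4 members of each list. The groups, comparisons, tests, lists and this rule were chosen before the data were examined.

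The alternatives were array weights, a mean-variance trend with a robust prior, every probe set, leaving out genes below the 30th percentile in all groups, a change of at least 2-fold, a test against 1.2-fold, median centring, quantile normalization of the named probe sets, the mean of a gene's probe sets, the replicate number as a block, leaving out each array, only the arrays of the compared groups, camera with an estimated correlation, fry, other references, a signature from lung endothelial cells alone, and scores from scaled genes or list medians. The deposited values without quantile normalization, and the transcription factor list without the presumed factors, were added after the data were seen. The fits were tested on simulated data with known changes. Raw probe intensities were not analysed here.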

Results

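The series measured gene expression in mouse skin fibroblasts before and after conversion to endothelial cells, in 12 arrays. The groups were skin fibroblasts (n = 2), mock-infected skin fibroblasts (n = 3), induced endothelial cells (n = 3), primary lung endothelial cells (n = 2) and the endothelial line MS-1 (n = 2). Array signals are given in log2 units, and differences as the first group minus the second with their standard error. Before normalization the median signal per array lay between 7.664 and 7.847 and the highest between 14.45 and 14.68. The number of arrays limits the precision.

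Induced endothelial cells were compared with mock-infected fibroblasts to measure the effect of the transferred factors, both groups being in the same medium. Genes of endothelial cells were among those with the largest rise: Emcn, a sialomucin of the endothelial surface, was higher by 5.63 ± 0.614 (adjusted p = 0.000921, limma), Myct1, an endothelial membrane protein, by 5.04 ± 0.232 (2.58e-06), and Cdh5, the cadherin of endothelial junctions, by 4.56 ± 0.702 (0.00737). Emcn (7.46, 5.52 and 6.08) and Myct1 (5.95, 6.04 and 6.1) were dim in mock-infected fibroblasts, so background limits the size of their rise. Cdh5 stood at 12.85 ± 0.779 (SD, n = 3) in the converted cells and at 8.29 ± 1.76 (SD, n = 3) in the mock-infected ones. Tek, the angiopoietin receptor Tie2 whose promoter drove the reporter of these mice, rose by 3.25 ± 0.214 (3.72e-05). Against untreated skin fibroblasts its rise was smaller, since Tek was lower in mock-infected than in untreated cells (both given below). The collagen gene Col1a1 did not pass and differed by -0.34 ± 0.153 (0.309), nor did Acta2, smooth muscle actin, at 0.01 ± 0.162 (0.983), or the pluripotency factor Pou5f1 at -0.01 ± 0.124 (0.978).

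All 5 presumed factors were higher in the converted cells. Etv2, an ETS factor that starts the blood and endothelial programme in the embryo, rose by 4.29 ± 0.206 (adjusted p = 3.3e-06), Lmo2, an adaptor of blood and endothelial transcription complexes, by 3.91 ± 0.153 (9.78e-07), and its partner Tal1 by 3.52 ± 0.159 (2.44e-06). Foxo1, a forkhead factor, rose by 1.69 ± 0.187 (0.000957) and Klf2, which responds to blood flow, by 1.43 ± 0.234 (0.00997). The list median was 3.53 (camera adjusted p = 2.33e-15, and 0.0187 with an estimated correlation), and all 5 passed when adjusted over the list alone. If these were the transferred factors, their rise was built into the experiment, and the list's tests say nothing about conversion. Etv2 averaged 11.62 in the converted cells and 7.33 in the mock-infected, 7.39 in lung endothelial cells and 7.54 in MS-1. The arrays do not separate transcripts of a transferred factor from those of the cell's own gene.

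**Figure D1:**
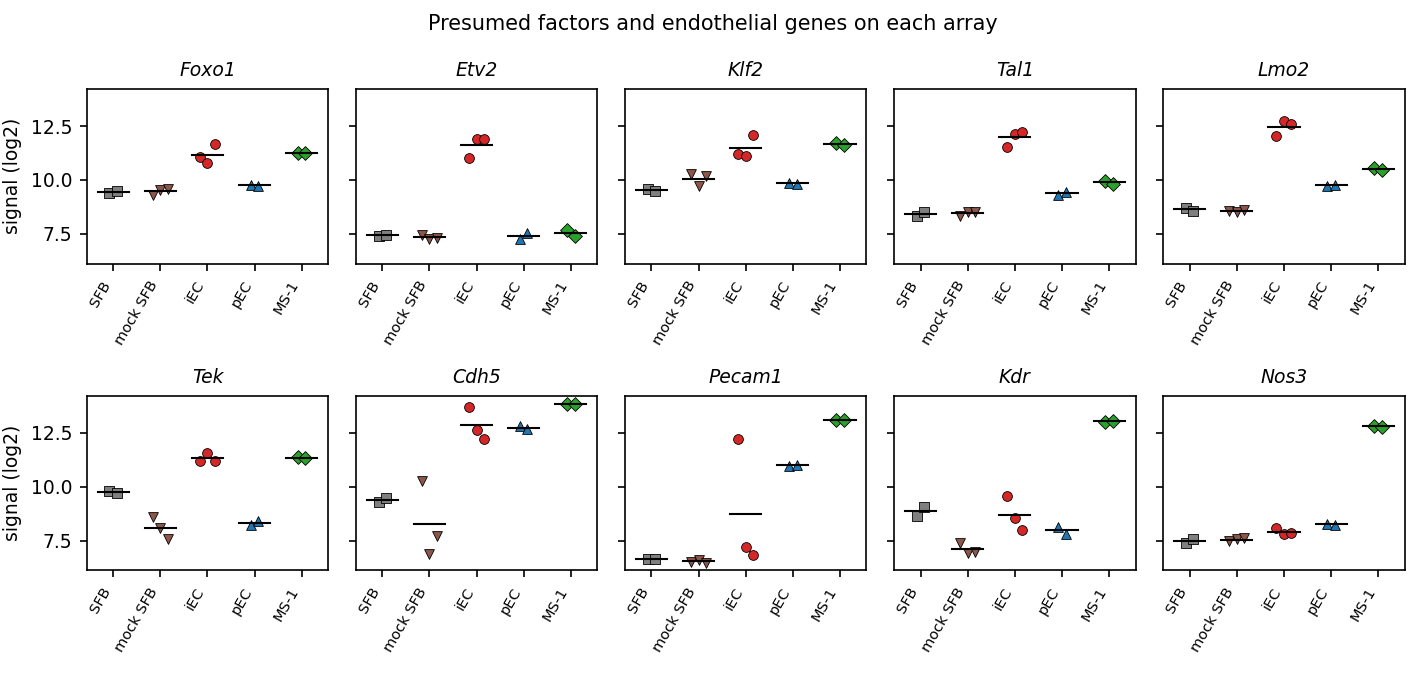
Array signal (log2) of the 5 presumed factors and of 5 endothelial genes; each point is an array, grouped as skin fibroblasts (SFB), mock-infected fibroblasts (mock SFB), induced endothelial cells (iEC), lung endothelial cells (pEC) and MS-1, and the bars are group means. Etv2 averaged 11.62 in iEC and 7.33 in mock SFB, while Pecam1 reached 12.22 on the array of iEC replicate 1 and 7.22 and 6.81 on the others.

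Among 43 measured endothelial identity genes 23 rose, 0 fell and 20 did not pass (30 rose when adjusted over the list alone), with a median of 1.73 (camera adjusted p = 1.11e-33, and 0.0187 with an estimated correlation). Podxl, an anti-adhesive sialomucin, rose by 3.98 ± 0.234 (1.58e-05). Kdr, the main VEGF receptor, rose by 1.60 ± 0.325 (adjusted p = 0.0273), a call lost without mock-infected replicate 2 (0.102), mock-infected replicate 3 (0.0841) or induced replicate 2 (0.0649). Its signals were 9.55, 8.53 and 7.99 in induced and 7.39, 6.94 and 6.95 in mock-infected cells. Untreated skin fibroblasts had 8.63 and 9.07, so the rise brought Kdr back to about their level. The adhesion molecule Pecam1 differed by 2.21 ± 1.09 (0.364), with signals of 12.22, 7.22 and 6.81 in induced replicates 1, 2 and 3. Nos3, endothelial nitric oxide synthase, differed by 0.37 ± 0.0943 (0.0684) and Vwf, von Willebrand factor, by 0.02 ± 0.0769 (0.94). Of 24 endothelial transcription factors 12 rose and 0 fell (13 rose and 1 fell when adjusted over the list alone), with a median of 1.02 (camera adjusted p = 2.2e-17, and 0.0123 with an estimated correlation), against a median of 0.65 without induced replicate 1. Sox7, a SOX factor of vascular development, rose by 3.39 ± 0.142 (1.47e-06). Without the presumed factors, 7 of the 19 remaining members rose (median 0.64, camera p = 8.54e-10, and p = 0.022 with an estimated correlation).

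Vessel subtype lists had few genes that passed. Of 12 venous and lymphatic genes 3 rose and 0 fell (4 when adjusted over the list alone; camera adjusted p = 0.001, and adjusted p = 0.147 with an estimated correlation). Without induced replicate 1 the venous and lymphatic median was 0.218 where all arrays gave 0.405, and 2 genes rose when any other induced or mock-infected array was left out. Lyve1, a hyaluronan receptor of lymphatic endothelium and macrophages, rose by 3.91 ± 0.496 (0.00227) and Flt4, the lymphatic VEGF receptor, by 2.38 ± 0.283 (0.00149). Of 16 arterial and Notch genes 3 rose and 0 fell (7 and 1 when adjusted over the list alone; camera adjusted p = 3.27e-05, and adjusted p = 0.396 with an estimated correlation); 6 rose without mock-infected replicate 1, 0 without mock-infected replicate 2 (median 0.44, from 0.69), and 1 without induced replicate 1 (median 0.39) or 2. Of 18 sprouting genes 3 rose and 1 fell (7 and 1 when adjusted over the list alone; camera adjusted p = 0.0251, and adjusted p = 0.427 with an estimated correlation). Pdgfb, which recruits pericytes, rose by 2.25 ± 0.313 (0.00415), and the vasodilator peptide gene Adm fell by 0.73 ± 0.0886 (0.00174). The sprouting call was lost without mock-infected replicate 3 (0.0709) or induced replicate 2 (0.065), and 5, 1, 1 and 6 genes rose without mock-infected replicates 1, 2 and 3 and induced replicate 3. In the lung capillary list 4 of 15 genes rose and 0 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.155, and 0.028 without mock-infected replicate 2); 2 rose without induced replicate 1 or 2, and 2 fell without mock-infected replicate 1. They included Hpgd, which breaks down prostaglandins, at 3.73 ± 0.343 (0.000348) and Car4, a carbonic anhydrase of capillaries, at 2.66 ± 0.409 (0.00736). On the lung endothelial arrays Hpgd stood at 7.14 and 7.63 and Car4 at 6.76 and 6.68, below every induced array. Hpgd was also at 8.93 and 8.86 in untreated skin fibroblasts, above the mock-infected 6.83, 6.64 and 7.27.

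Of 36 fibroblast genes 1 rose and 0 fell (1 and 2 when adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00233 downwards, and adjusted p = 0.558 with an estimated correlation). The 1 that rose was Pi16, a marker of adventitial fibroblasts, by 3.06 ± 0.378 (0.00192). The list's call was lost without induced replicate 1 (0.232), and 4 members fell without mock-infected replicate 1, 4 without induced replicate 3 and 1 without induced replicate 2. Col1a2 differed by -0.33 ± 0.169 (0.38), the surface glycoprotein Thy1 by 0.11 ± 0.232 (0.892) and S100a4 by -0.48 ± 0.186 (0.227). None of the 15 contractile genes (camera adjusted p = 0.137) or the 8 mesenchymal transition factors (0.392) passed over all genes; 0 and 1 fell when adjusted over the list alone. The contractile list was called downwards without mock-infected replicate 3 (0.000897, median -0.30) or induced replicate 3 (0.00313, median -0.44, with 1 that fell). The contractile genes Actg2 and Cnn1 differed by -1.54 ± 0.875 and -1.34 ± 0.706 (0.447 and 0.4), and Twist1, a mesenchymal factor, by -0.43 ± 0.115 (0.0787).

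**Figure D2:**
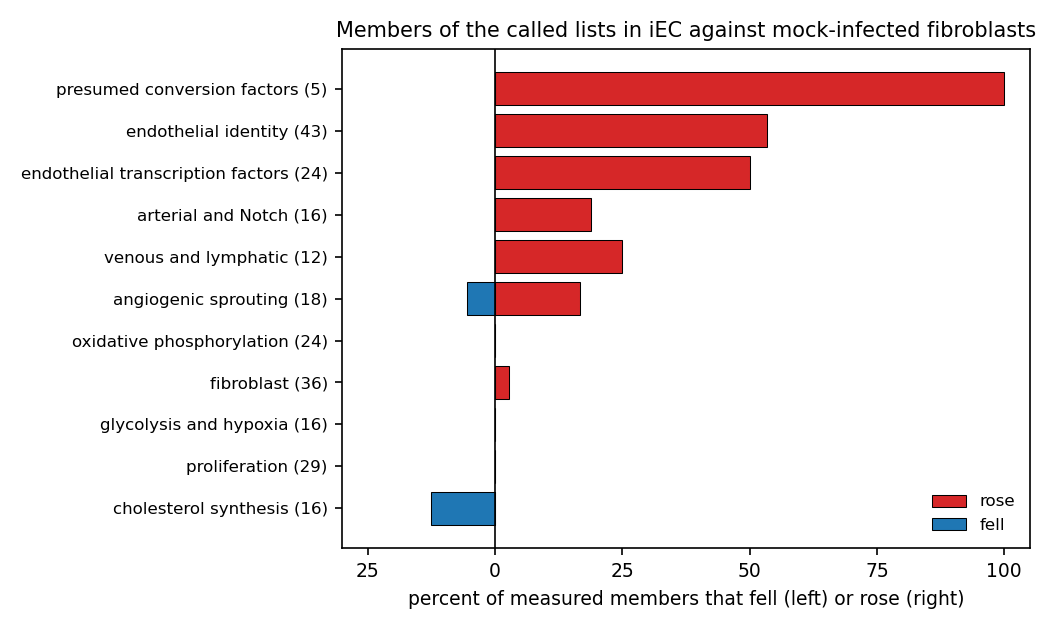
Percent of the measured members of each called list (number measured in parentheses) that rose, to the right, or fell, to the left, in induced endothelial cells against mock-infected fibroblasts at an adjusted p below 0.05. The bars show 23 of 43 endothelial identity genes and 12 of 24 endothelial transcription factors that rose, and 1 of 36 fibroblast genes.

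Metabolic and growth lists had lower medians in the converted cells. Cholesterol synthesis had a median of -0.70 (camera adjusted p = 1.57e-08, and adjusted p = 0.486 with an estimated correlation), and 2 of its 16 genes fell (10 when adjusted over the list alone). Hmgcs1, an early enzyme of the pathway, fell by 0.94 ± 0.219 (0.0485), but its p was 0.132, 0.137, 0.108 and 0.151 without mock-infected replicates 2 and 3 and induced replicates 1 and 2. The list's count was 0 when any 1 of those 4 arrays was left out, 6 without mock-infected replicate 1 and 10 without induced replicate 3. For 29 proliferation genes the median was -0.32 (camera adjusted p = 8.7e-05, and adjusted p = 0.602 with an estimated correlation; 0 passed, also when adjusted over the list alone). The spindle gene Cenpf differed by -0.76 ± 0.187 (0.0588). That list's call was lost without mock-infected replicate 1 (median -0.12, adjusted p = 0.234, with 1 that fell). Without induced replicate 2 the median was -0.14 (0.0395), and 2 fell without induced replicate 1 or 3. Glycolysis and hypoxia (16 genes, median -0.17, camera adjusted p = 8.7e-05, and adjusted p = 0.052 with an estimated correlation) had 0 that passed and 6 that fell when adjusted over the list alone; 2 fell without mock-infected replicate 1 and 1 without each induced replicate. Oxidative phosphorylation (24 genes, median -0.16, 0.00407, and adjusted p = 0.558 with an estimated correlation) had 0 that passed and 3 that fell when adjusted over the list alone. Its call was lost without mock-infected replicate 1 (0.0997) or induced replicate 3 (0.0819), and 2 fell without induced replicate 1.

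The other lists were not called with all arrays. Single members rose in the lists of TGF-beta targets (13 genes; Tgfb2, a TGF-beta ligand, by 1.43 ± 0.174) and p53 and senescence (12; Eda2r, a TNF-family receptor, by 0.66 ± 0.0776), with the same counts when adjusted over the list alone. Of 18 inflammatory and adhesion genes 1 rose and 1 fell, also when adjusted over the list alone, and 0 fell without any 1 of the induced arrays or mock-infected replicates 2 and 3; the adhesion molecule Sele rose by 2.10 ± 0.243. Of 17 haematopoietic genes 1 rose and of 15 pluripotency genes 1 fell, in both cases also when adjusted over the list alone. The first count was 0 without mock-infected replicate 2 or 3, and the second was 0 without mock-infected replicate 2 or induced replicate 2. Nanog differed by -0.10 ± 0.0946 (adjusted p = 0.695). Of 19 macrophage and leukocyte genes Cd14, a receptor for bacterial lipopolysaccharide, rose by 1.77 ± 0.353 (adjusted p = 0.0257; 0.0868 without mock-infected replicate 2 and 0.0626 without induced replicate 2), and 3 rose when adjusted over the list alone. Of 12 pericyte and smooth muscle genes 1 rose and 2 fell, also when adjusted over the list alone; with any 1 induced or mock-infected array left out 1 fell, and 0 rose except without induced replicate 3. Of 12 imprinted genes Mest, a paternally expressed hydrolase, rose by 3.36 ± 0.341, and Dlk1, a Notch ligand of the same class, fell by 3.15 ± 0.636, also when adjusted over the list alone. Dlk1 had an adjusted p of 0.027, which was 0.107, 0.0873, 0.0657 and 0.0888 without mock-infected replicates 2 and 3 and induced replicates 1 and 2.

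Leaving out 1 array brought calls in several of the uncalled lists. Interferon response was called upwards without induced replicate 2 (adjusted p = 0.000789, median 0.55) or 3 (0.0104, 0.47) and downwards without induced replicate 1 (0.015, -0.24). TGF-beta targets were called without mock-infected replicate 1 (0.0444, with 5 that rose and 1 that fell), and p53 and senescence without mock-infected replicate 2 (0.025) or induced replicate 2 (0.0356). Inflammatory and adhesion genes were called without induced replicate 3 (0.0116, with 3 that rose), and keratinocyte genes without induced replicate 1 (0.0356). Macrophage and leukocyte genes that rose numbered 3 without mock-infected replicate 1, where 2 interferon genes rose and 1 fell.

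No member passed in limma over all genes in the lists of BMP and ALK1 targets (12 genes), interferon response (21), antigen presentation (12), early mesoderm (12), lung epithelium (16), mesothelium (7), keratinocyte (12), melanocyte and Schwann (10), adipocyte (10), skeletal muscle (10), Hox position code (38) and sex-linked genes (4). When adjusted over the list alone, 1 BMP and ALK1 target, 1 interferon gene and 2 mesothelium genes rose, and 0 genes of the others. Examples below the threshold were the antiviral gene Oas2 at 1.23 ± 0.292 (adjusted p = 0.0505), Upk1b, a uroplakin of mesothelium, at 2.28 ± 0.745 (0.147) and Hoxd10 at 1.68 ± 0.587 (0.178). Median and test differed in sign for lung capillary (median -0.01, upwards) and mesenchymal transition factors (0.03, downwards); median and mean did so for melanocyte and Schwann (0.07 and -0.02), antigen presentation (-0.02 and 0.00), skeletal muscle (-0.05 and 0.01) and Hox position code (-0.02 and 0.03).

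In all, 655 of 19938 genes passed between converted and mock-infected cells, 492 higher and 163 lower, and 231 and 58 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 3227. The groups did not overlap for any of the 655, which a low p all but ensures; among genes taken regardless of p chance gives it in 10% with 3 against 3 arrays. Genes outside the lists with the largest change were Ceacam1, an adhesion molecule of epithelium and vessels, at 4.14 ± 0.458 (adjusted p = 0.000957), the GTPase Gimap6 at 3.96 ± 0.14 (6.26e-07) and Lrrc55, a potassium channel subunit, at 3.87 ± 0.277 (5.96e-05). Their mock-infected signals were dim, such as 6.64, 6.69 and 7.04 for Gimap6, so the sizes of these rises give no rank. Galnt13, a glycosyltransferase, fell by 2.30 ± 0.361 (0.00822), the matrix protein gene Edil3 fell by 2.25 ± 0.36 (0.00904) and Plac8 fell by 2.12 ± 0.324 (0.00715). The count was 1303 without mock-infected replicate 1, 309 without mock-infected replicate 2, 406 without mock-infected replicate 3, 351 without induced replicate 2 and 1131 without induced replicate 3. It was 114 (107 higher) with only these 6 arrays, whose replicates differed more than those of skin fibroblasts or MS-1, 2281 with array weights, 289 at 2-fold or more and 211 in a test against 1.2-fold.

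Induced endothelial cells were also compared with the starting skin fibroblasts, which differed in medium too. Lcn2, a secreted iron-carrier protein of inflammation, was higher by 6.61 ± 0.475 (adjusted p = 5.1e-05), Emcn by 5.58 ± 0.687 (0.00097) and Lilrb4a, an inhibitory receptor of myeloid cells, by 4.89 ± 0.607 (0.00101). Scn7a, a sodium channel, fell by 4.24 ± 0.535 (0.00113) and Lgr5, a receptor for R-spondins, fell by 3.91 ± 0.244 (1.8e-05). All 5 presumed factors rose, Etv2 by 4.19 ± 0.23 (8.89e-06) and Klf2 by 1.93 ± 0.261 (0.00169). Tek rose by 1.57 ± 0.239 (0.00318), Kdr differed by -0.16 ± 0.363 (0.843), and Col1a1 fell by 1.15 ± 0.171 (0.00274). Of the endothelial identity genes 22 of 43 rose and 0 fell (29 and 1 when adjusted over the list alone; camera adjusted p = 0.0378 with an estimated correlation). Of 18 inflammatory and adhesion genes 9 rose and 0 fell (11 and 1 when adjusted over the list alone; 0.0449 with an estimated correlation), among them the chemokine Cxcl1 by 3.60 ± 0.3 (0.000106) and the cytokine Il6 by 3.52 ± 0.344 (0.000276).

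Lists lower than in skin fibroblasts included fibroblast genes and cholesterol synthesis. Of 36 fibroblast genes 17 fell and 1 rose (20 and 1 when adjusted over the list alone; median -0.80, camera adjusted p = 1.88e-08, and adjusted p = 0.248 with an estimated correlation), but 5 fell without skin fibroblast replicate 1, 4 without skin fibroblast replicate 2 and 10 without induced replicate 1. Of 16 cholesterol genes 11 fell (15 when adjusted over the list alone; median -1.35, camera adjusted p = 5.69e-11, and adjusted p = 0.248 with an estimated correlation), against 2, 2 and 7 without skin fibroblast replicates 1 and 2 and induced replicate 2. Hmgcs1 fell by 1.98 ± 0.245 (0.000972) and Insig1, which holds back sterol regulators, fell by 1.88 ± 0.291 (0.00353). The intermediate filament gene Des fell by 1.30 ± 0.112 (0.000142). In total 1967 genes passed, 812 higher and 1155 lower, of which 374 and 361 changed at least 2-fold. The count was 573 and 478 without skin fibroblast replicates 1 and 2, 1281 without induced replicate 2, 1139 with only these 5 arrays, 735 at 2-fold or more, 721 in a test against 1.2-fold and 5676 with array weights. With median-centred arrays 605 were higher and 1961 lower, so the split between directions depended on the scaling.

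Mock-infected and untreated skin fibroblasts were compared for the effect of infection and medium without the factors. Lcn2 rose by 5.61 ± 0.475 (adjusted p = 0.000328), the acute-phase protein gene Saa3 by 4.32 ± 0.42 (0.000681), Cxcl1 by 2.98 ± 0.3 (0.000839) and Penk, the precursor of enkephalin, by 3.42 ± 0.415 (0.00218). Lgr5 fell by 4.05 ± 0.244 (5.5e-05), Scg2, a secretory granule protein gene, fell by 4.33 ± 0.333 (0.000237), and Aspn, a small proteoglycan gene of connective tissue, fell by 3.67 ± 0.452 (0.00237). None of the presumed factors passed: Etv2 differed by -0.10 ± 0.23 (0.879) and Klf2 by 0.50 ± 0.261 (0.346). Tek fell by 1.68 ± 0.239 (0.00508), a call lost without skin fibroblast replicate 1 (0.0585) or 2 (0.0702). Of 18 inflammatory and adhesion genes 6 rose and 0 fell (9 when adjusted over the list alone; median 0.52, camera adjusted p = 2.31e-07, and adjusted p = 0.212 with an estimated correlation), and 3 rose without skin fibroblast replicate 2. Of 36 fibroblast genes 6 fell (9 when adjusted over the list alone; median -0.42, camera adjusted p = 2.9e-05, and adjusted p = 0.703 with an estimated correlation), against 1 and 0 without skin fibroblast replicates 1 and 2 and 2 and 3 without mock-infected replicates 2 and 3.

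In that comparison 782 genes passed, 206 higher and 576 lower, and 82 and 199 changed at least 2-fold. The count was 173 and 99 without skin fibroblast replicates 1 and 2, 1214 and 420 without mock-infected replicates 1 and 2, 284 with only these 5 arrays, 281 at 2-fold or more, 194 in a test against 1.2-fold and 2993 with array weights. Median centring gave 163 higher and 1750 lower, and moved the median of all genes to -0.12; quantile normalization of the named probe sets gave 265 and 449.

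**Figure D3:**
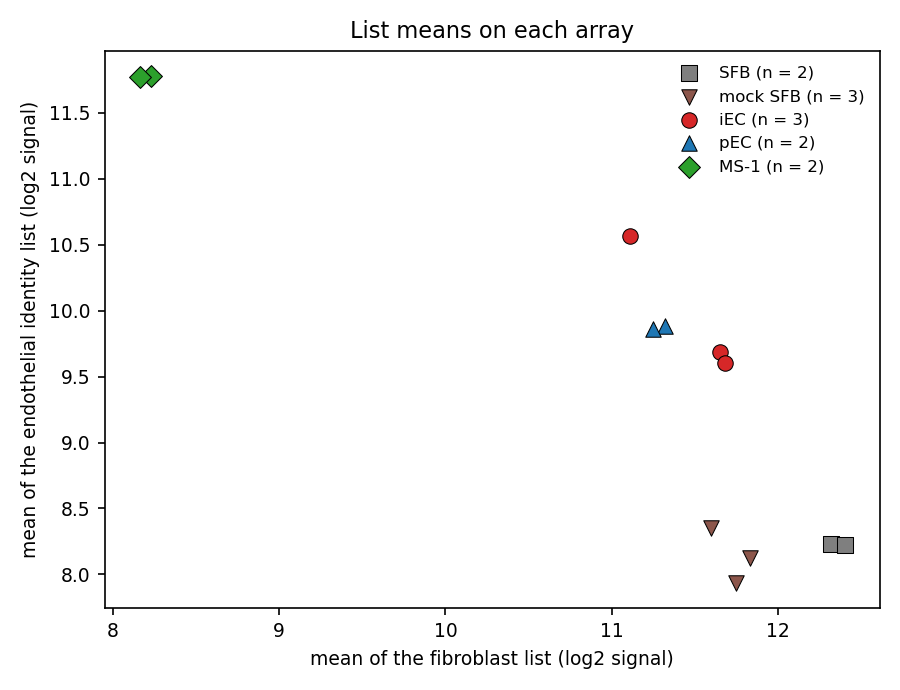
Mean signal (log2) per array over the 43 endothelial identity genes (vertical) and the 36 fibroblast genes (horizontal); each point is an array, with its group given by colour and shape. Induced endothelial cells (iEC) averaged 9.95 and lung endothelial cells (pEC) 9.87 on the endothelial list, above both fibroblast groups, while on the fibroblast list they averaged 11.48 and 11.29 and MS-1 8.20.

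Lung endothelial cells were compared with skin fibroblasts as a reference for the natural difference, although medium and organ differed too. Mock infection with the change of medium already gave 782 genes, so part of this difference may come from the medium. Emcn was higher by 6.79 ± 0.753 (adjusted p = 6e-04), Myct1 by 5.45 ± 0.284 (7.63e-06), Bmx, a kinase of arterial endothelium, by 4.50 ± 0.658 (0.00283) and Hey2, a Notch target of arteries, by 3.39 ± 0.308 (0.000187). Lower were the chemokine Ccl8 by -5.72 ± 0.343 (1.86e-05), the matrix gene Abi3bp by -5.50 ± 0.526 (0.000259) and Hoxc8, a position gene of the trunk, by -4.70 ± 0.309 (2.89e-05). Pecam1 was at 10.98 and 11.02 against 6.63 and 6.65, a difference of 4.36 ± 1.34 that did not pass (0.0806) in a model whose spread also came from the induced cells, at 12.22, 7.22 and 6.81. Nos3 rose by 0.76 ± 0.115 (0.00364). Not every endothelial gene was higher: Kdr stood at 8.14 and 7.8 in lung endothelial cells and at 8.63 and 9.07 in skin fibroblasts. Tek was not higher either, since induced cells exceeded lung endothelial cells in Tek by more than they exceeded skin fibroblasts. Etv2 differed by -0.04 ± 0.252 (0.95). Of 43 endothelial identity genes 23 rose and 1 fell (30 and 2 when adjusted over the list alone; median 1.28, camera adjusted p = 9.27e-16, and adjusted p = 0.114 with an estimated correlation), against 9 and 9 that rose without skin fibroblast replicates 1 and 2 and 12 and 8 without lung endothelial replicates 1 and 2, and 0 that fell without the first 3 of these. Of 36 fibroblast genes 16 fell (25 fell and 1 rose when adjusted over the list alone; median -0.80, camera adjusted p = 3.79e-14, and adjusted p = 0.149 with an estimated correlation), against 9 and 7 without skin fibroblast replicates 1 and 2 and 9 without lung endothelial replicate 2. Pdgfra, the PDGF receptor of fibroblasts, fell by 2.65 ± 0.344 (0.00145).

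Markers of other cell types moved with the lung endothelial arrays. Of 7 mesothelium genes 4 rose (5 when adjusted over the list alone; camera adjusted p = 0.000101, and adjusted p = 0.26 with an estimated correlation), against 2 and 1 without skin fibroblast replicates 1 and 2. Nkain4, a membrane protein gene of mesothelium, rose by 3.92 ± 0.483 (0.00104). Of 19 macrophage and leukocyte genes 9 rose (13 when adjusted over the list alone; median 1.15, camera adjusted p = 4.14e-07, and adjusted p = 0.303 with an estimated correlation), against 0 and 0 without skin fibroblast replicates 1 and 2 and 4 without lung endothelial replicate 2. Upk3b, a mesothelial uroplakin, stood at 11.59 and 9.02 in lung endothelial replicates 1 and 2, and Tyrobp, a signalling adaptor of myeloid cells, at 8.79 and 10.61. In the Hox list 8 genes rose and 9 fell. In total 1587 genes passed, 750 higher and 837 lower, of which 376 and 382 changed at least 2-fold. The count was 499 and 405 without skin fibroblast replicates 1 and 2, 948 and 554 without lung endothelial replicates 1 and 2, 3330 with only these 4 arrays, 3658 with array weights, 758 at 2-fold or more and 639 in a test against 1.2-fold. Median centring gave 617 higher and 1151 lower.

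**Figure D4:**
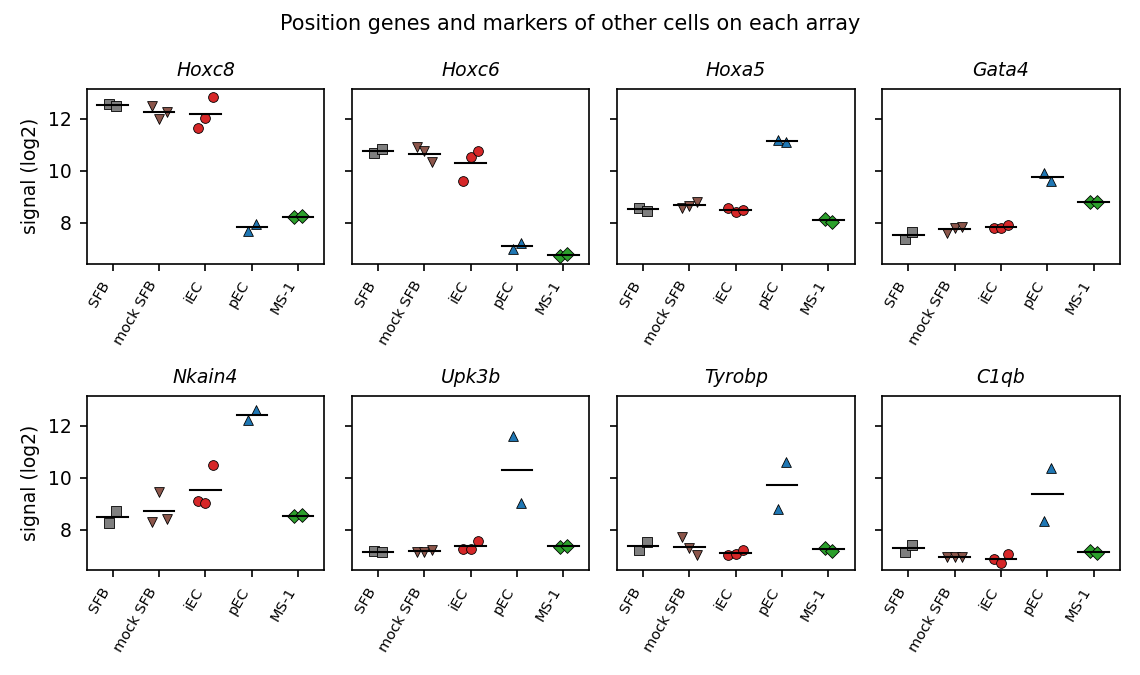
Array signal (log2) of the position genes Hoxc8, Hoxc6, Hoxa5 and Gata4, of the mesothelial genes Nkain4 and Upk3b and of the myeloid genes Tyrobp and C1qb; each point is an array, grouped as in the plot of the presumed factors, and the bars are group means. Hoxc8 averaged 12.17 in iEC and 7.83 in pEC, and Tyrobp stood at 8.79 and 10.61 on the pEC arrays.

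Lung endothelial cells were compared with mock-infected fibroblasts, both in endothelial medium. Emcn was higher by 6.84 ± 0.687 (adjusted p = 0.000339), Bmp4, a bone morphogenetic protein, by 5.67 ± 0.867 (0.00436) and Mest by 5.34 ± 0.382 (3.88e-05). The chemokine Cxcl5 fell by 5.59 ± 0.503 (0.000169), Saa3 fell by 5.53 ± 0.42 (5.86e-05) and the chemokine Ccl11 fell by 4.52 ± 0.474 (0.000448). Col1a1 averaged 13.00 in both groups. Of 16 glycolysis and hypoxia genes 4 fell (11 when adjusted over the list alone; median -0.46, camera adjusted p = 0.0155 with an estimated correlation), or 7 without mock-infected replicate 1; Bnip3, a hypoxia-induced mitochondrial gene, fell by 1.21 ± 0.158 (0.0018). Of 43 endothelial identity genes 21 rose (30 when adjusted over the list alone; camera adjusted p = 1.29e-17, and adjusted p = 0.132 with an estimated correlation), against 13 and 8 without lung endothelial replicates 1 and 2. In total 1234 genes passed, 779 higher and 455 lower, with 388 and 228 changed at least 2-fold. The count was 2466 and 807 without mock-infected replicates 1 and 3, 724 and 432 without lung endothelial replicates 1 and 2, 635 with only these 5 arrays, 616 at 2-fold or more, 527 in a test against 1.2-fold and 2444 with array weights.

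Induced and primary lung endothelial cells, in the same medium, were compared for what still separated them. Higher in the induced cells were Cxcl5 by 5.41 ± 0.503 (adjusted p = 0.00023), Saa3 by 5.07 ± 0.42 (0.000123), Hoxc8 by 4.34 ± 0.282 (2.53e-05), the joint lubricant gene Prg4 by 4.33 ± 0.476 (0.000694) and Etv2 by 4.23 ± 0.23 (8.84e-06). Lower were the neuronal membrane glycoprotein gene Gpm6a by -4.66 ± 0.333 (4.02e-05), the TNF-family ligand Tnfsf18 by -4.37 ± 0.302 (3.39e-05), the microtubule protein gene Map2 by -4.00 ± 0.166 (1.93e-06) and Hey2 by -2.78 ± 0.282 (0.000396). Cdh5 differed by 0.11 ± 0.785 (0.956) and Kdr by 0.72 ± 0.363 (0.277), while Tek was higher in the induced cells by 3.01 ± 0.239 (8.92e-05). In Kdr and Tek the lung endothelial cells were themselves not above skin fibroblasts. Of the position genes, Hoxc6 was higher by 3.19 ± 0.284 (0.000181) and Hoxa5 lower by -2.65 ± 0.0982 (1.8e-06).

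Of 43 endothelial identity genes 8 were higher in the induced than in the lung endothelial cells and 1 lower (9 and 5 when adjusted over the list alone; median 0.05, camera adjusted p = 0.0446 upwards, and adjusted p = 0.573 with an estimated correlation). Without induced replicate 1 the list was not called (0.214), with 7 higher and 13 lower. It was also not called without lung endothelial replicate 2 (0.0511), and 0 were lower without induced replicate 2 or either lung endothelial array. Of 7 mesothelium genes 3 were lower (5 when adjusted over the list alone; median -2.86, camera adjusted p = 0.000547, and adjusted p = 0.275 with an estimated correlation). Of 19 macrophage and leukocyte genes 7 were lower and 1 higher (11 and 2 when adjusted over the list alone; camera adjusted p = 1.69e-05, and adjusted p = 0.345 with an estimated correlation), with 11 lower without lung endothelial replicate 1, and 0 higher without that array, lung endothelial replicate 2 or induced replicate 2. Laptm5, a lysosomal protein gene of blood cells, was lower by -2.49 ± 0.379 (0.00453). In total 1502 genes passed, 677 higher and 825 lower, with 321 and 286 at 2-fold or more. The count was 705 without induced replicate 2, 848 and 404 without lung endothelial replicates 1 and 2, 379 with only these 5 arrays, 607 at 2-fold or more, 439 in a test against 1.2-fold and 3853 with array weights.

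MS-1 cells were compared with skin fibroblasts, both in the same basal medium, as another endothelial reference. Emcn was higher by 7.14 ± 0.753 (adjusted p = 4.51e-05), Pecam1 by 6.44 ± 1.34 (0.00383), Nos3 by 5.31 ± 0.115 (1.27e-09) and Kdr by 4.17 ± 0.398 (2.25e-05). Periostin (Postn) fell by 7.61 ± 0.259 (1.56e-08), the collagen cross-linking enzyme Lox fell by 7.60 ± 0.126 (2.25e-10) and Acta2 fell by 6.07 ± 0.199 (1.32e-08). Of 43 endothelial identity genes 38 rose and 1 fell, and of 36 fibroblast genes 0 rose and 33 fell (medians 3.74 and -4.21; camera adjusted p = 0.0422 for both with an estimated correlation). Of 29 proliferation genes 26 rose (27 when adjusted over the list alone; median 1.32, camera adjusted p = 2.52e-11, and adjusted p = 0.295 with an estimated correlation), among them the replication gene Mcm6 by 2.21 ± 0.335 (0.000542). In total 6692 genes passed, 3136 higher and 3556 lower, with 1086 and 1804 at 2-fold or more. The count was 4398 without MS-1 replicate 2, 2890 at 2-fold or more, 4046 in a test against 1.2-fold, 10449 with only these 4 arrays and 10797 with array weights. Quantile normalization of the named probe sets gave 4328 higher and 3236 lower.

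Induced endothelial cells were compared with MS-1 cells, again in different media. The induced cells had higher signals of matrix genes: Lox differed by 7.52 ± 0.115 (adjusted p = 1.08e-10), the proteoglycan gene Dcn by 7.31 ± 0.183 (2.1e-09) and Col1a1 by 4.03 ± 0.171 (7.19e-08). Nos3 was lower by -4.89 ± 0.105 (9.43e-10), the tight junction gene Cldn5 by -4.53 ± 0.11 (1.92e-09) and Kdr by -4.34 ± 0.363 (1.07e-05). Tek differed by -0.01 ± 0.239 (0.975), and Cdh5 did not pass (0.4). Of 43 endothelial identity genes 5 were higher and 26 lower (5 and 28 when adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), and of 36 fibroblast genes 31 were higher (32 when adjusted over the list alone; adjusted p = 0.0846 with an estimated correlation), with 1 lower without induced replicate 3. In total 5903 genes passed, 2955 higher and 2948 lower, with 1431 and 882 at 2-fold or more. The count was 3648 and 3589 without MS-1 replicates 1 and 2, 2313 at 2-fold or more, 3366 in a test against 1.2-fold and 9074 with array weights. Median centring gave 2527 higher and 3309 lower and moved the median of all genes to -0.10. Quantile normalization of the named probe sets gave 2759 and 3868, so the split between directions depended on the scaling.

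The endothelial references themselves differed widely. MS-1 cells exceeded lung endothelial cells in Kdr by 5.06 ± 0.398 (adjusted p = 7.98e-06), Nos3 by 4.55 ± 0.115 (4.93e-09), the urea transporter gene Slc14a1 by 5.95 ± 0.419 (3.54e-06) and Tek by 3.03 ± 0.262 (1.6e-05). They were lower in Lox by -7.37 ± 0.126 (2.53e-10), the glypican Gpc4 by -6.74 ± 0.211 (1.35e-08) and Hey2 by -3.78 ± 0.308 (1.05e-05). Of 36 fibroblast genes 28 were lower (31 when adjusted over the list alone; median -3.57, adjusted p = 0.0844 with an estimated correlation). Of 21 interferon genes 19 were higher (20 when adjusted over the list alone; median 2.38, camera adjusted p = 3.44e-09, and adjusted p = 0.315 with an estimated correlation), and 11 without MS-1 replicate 1 or 2 or lung endothelial replicate 2; Irf7, a regulator of interferon genes, was higher by 3.75 ± 0.472 (0.000214). In total 5658 genes passed, 2648 higher and 3010 lower, with 815 and 1479 at 2-fold or more. The count was 3699 and 3393 without MS-1 replicates 1 and 2, 2294 at 2-fold or more and 3213 in a test against 1.2-fold. Quantile normalization of the named probe sets gave 3665 higher and 2747 lower.

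The change on conversion was set against the difference between lung endothelial cells and skin fibroblasts, which shares no array with it. That difference also holds any effect of medium and organ. Of 19938 genes 128 were higher in both comparisons, where independence would give 18.5. Another 39 were lower in both, where it would give 6.84. Both comparisons take the spread of a gene from the same model, so genes with a small spread pass more easily in both. The numbers under independence may therefore be too low a baseline. In opposite directions 26 genes moved, and since no expected number was calculated for them, these cannot be called few. Emcn, Myct1 and Sox7 were among those higher in both. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.318 and a Spearman rho of 0.105. The count of 167 genes moving the same way was 60 and 59 without skin fibroblast replicates 1 and 2, 353 without mock-infected replicate 1, 290 without induced replicate 3, 91 and 71 without lung endothelial replicates 1 and 2, 69 with only the arrays of each comparison, and 572 with array weights. With MS-1 in place of lung endothelial cells the count was 392. But 6692 genes passed between MS-1 and skin fibroblasts, against 1587 for lung endothelial cells, so independence would also give more. That number was not calculated, so 392 does not show closer agreement than 167.

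A signature of 145 genes at least 2-fold higher, and 327 at least 2-fold lower, in lung endothelial cells and in MS-1 than in skin fibroblasts was then followed in converted against mock-infected cells. Here too the spread of a gene came from the same model in all comparisons, so the calls are not fully independent. Of the 145 endothelial genes 59 rose, 0 fell and 86 did not pass, with a median of 0.82 (camera p = 6.58e-44, and p = 0.00148 with an estimated correlation). Of the 327 fibroblast genes 23 fell, 3 rose and 301 did not pass, with a median of -0.26 (camera p = 1.11e-12, and p = 0.0997 with an estimated correlation). Their mean was 10.44 and 10.59 on the skin fibroblast arrays but already 9.528, 9.494 and 9.66 on the mock-infected ones. It was 8.918, 9.318 and 9.418 in induced and 8.579 and 8.442 in lung endothelial cells. Some of the 301, such as Lgr5, were already low in mock-infected fibroblasts, so they are not all fibroblast genes kept on conversion. The count of 59 was 33, 32 and 36 without skin fibroblast replicates 1 and 2 and lung endothelial replicate 2, 31 with only the arrays of each comparison and 100 with array weights. The count of 23 was 8 without either skin fibroblast array, 64, 13 and 13 without mock-infected replicates 1, 2 and 3, 63 without induced replicate 3 with the signature drawn anew, 12 and 9 without lung endothelial replicates 1 and 2, 13 and 12 without MS-1 replicates 1 and 2, 1 with only the arrays of each comparison and 99 with array weights. With the same 327 genes kept, 15, 15 and 49 fell without induced replicates 1, 2 and 3, with a median of -0.14 without replicate 1.

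The mean over the endothelial identity list was 9.95 ± 0.535 (SD, n = 3) in induced endothelial cells and 8.14 ± 0.207 (SD, n = 3) in mock-infected fibroblasts, a difference of 1.81 (exact two-sided permutation test, p = 0.1, the smallest p these arrays allow). It was 8.23 ± 0.00405 (SD, n = 2) in skin fibroblasts, 9.87 ± 0.0179 (SD, n = 2) in lung endothelial cells and 11.78 ± 0.0107 (SD, n = 2) in MS-1. The fibroblast list averaged 11.48 ± 0.322 (SD, n = 3) in induced cells and 11.73 ± 0.118 (SD, n = 3) in mock-infected fibroblasts, a difference of -0.24 (exact two-sided permutation test, p = 0.3), or -0.06 without induced replicate 1. It averaged 12.36 in skin fibroblasts, 11.29 in lung endothelial cells and 8.20 in MS-1.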

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

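The deposited values without a further quantile normalization, and the transcription factor list without the presumed factors, were tried only after the data were seen. Of 338 values under alternatives, 231 stayed and 107 did not. A count stayed if within 1.5 times, and r if within its spread over the fits without 1 array. A list score stayed if it kept its sign, so a score difference that shrank was counted as stayed. Of 16232 values of named genes under the alternatives 1715 lost their call, 148 gained one and 0 reversed. Unless a reason is given, the cause was not tested.

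With only the arrays of the compared groups the counts of genes passed were 114 (induced against mock-infected), 1139 (induced against skin fibroblasts), 284 (mock-infected against skin fibroblasts), 3330 (lung endothelial against skin fibroblasts), 635 (lung endothelial against mock-infected), 379 (induced against lung endothelial) and 10449 (MS-1 against skin fibroblasts). The spread then came from these groups alone: the SD of the difference between replicates was 0.1608 for skin fibroblasts, 0.1384 for MS-1 and 0.4217 for mock-infected replicates 1 and 2. The labels call the replicates biological; if those of skin fibroblasts and MS-1 were not independent cultures, the pooled spread behind all p-values would be too small. With that setting 69 genes moved the same way in the conversion and in the natural difference, and 31 endothelial and 1 fibroblast signature genes followed. Array weights gave 2281, 5676, 2993, 3658, 2444, 3853 and 10797 for the same comparisons, 9074 for induced cells against MS-1, 572 genes moving the same way (r = 0.255), and 100 and 99 signature genes. A change of at least 2-fold left 289, 735, 281, 758, 616, 607 and 2890 genes, then 2313 for induced cells against MS-1 and 2294 for MS-1 against lung endothelial cells. A test against 1.2-fold left 211, 721, 194, 639, 527, 439, 4046, 3366 and 3213; these are stricter by construction.

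Quantile normalization of the named probe sets turned the majority to higher for MS-1 against skin fibroblasts (4328 and 3236, from 3136 and 3556) and against lung endothelial cells (3665 and 2747, from 2648 and 3010). For induced cells against MS-1 it turned a near-even split to a majority lower (2759 and 3868, from 2955 and 2948). Median centring gave 1913 genes for mock-infected against skin fibroblasts. With every probe set r was 0.257. Against mock-infected fibroblasts as reference r was 0.421, where 50 simulated data sets with no change gave 0.447 from the shared arrays alone, but the covariance was 0.0767 against a simulated 0.0136. With that reference 213 genes moved the same way, 165 up and 48 down, where 19.2 and 3.72 would be expected if the 2 comparisons were independent. They share the mock-infected arrays, so they are not independent. The simulation gave a mean of 0, but no gene was changed in it and hardly any could pass, so it gives no baseline for this count. With MS-1 as reference 392 genes moved the same way, but 6692 genes passed between MS-1 and skin fibroblasts, and the number expected by independence was not calculated. The number of lists called with an estimated correlation was 3, 4, 0, 0, 1, 0, 4, 0 and 0 over the comparisons in the order above, against 11, 12, 7, 14, 18, 17, 16, 14 and 15. For induced cells against either fibroblast group, these included the presumed factors themselves and the transcription factor list that contains them. With fry the number of lists was 5 for induced against mock-infected cells, 4 for mock-infected against skin fibroblasts and 23 for MS-1 against lung endothelial cells. The replicate number as a block gave 40 fibroblast signature genes that fell and 621 genes for induced against mock-infected cells; deviations of arrays with the same number correlated at 0.0343, 0.0937 and -0.159, so the numbers did not pair them.

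Leaving out 1 array, where a lone array is assumed to vary like the other groups, gave counts from 309 to 1303 (induced against mock-infected), 478 to 2453, 99 to 1214, 405 to 948, 432 to 2466, 404 to 2019, 4398 to 4577, 3589 to 6001 and 3393 to 4226, in the same order. Genes moving the same way ranged from 59 to 353 and r from 0.234 to 0.375, and the signature genes from 32 to 82 (endothelial) and from 8 to 64 (fibroblast). The endothelial score difference ranged from 1.51 to 1.99 and the fibroblast one from -0.344 to -0.0573, lowest in size without induced replicate 1. Without that array the interferon list turned from a median of 0.24, not called, to -0.244 (adjusted p = 0.015), and the endothelial identity list in induced against lung endothelial cells from 8 higher and 1 lower to 7 and 13. Signal over background limits dim genes: without those below 7.06 in every group 14857 genes were left.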

Other observations

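The tests on induced replicate 1, on fibroblast, mesothelial and macrophage transcripts of the lung endothelial arrays, and on myeloid genes of the induced cells were chosen only after the results were seen.

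In 78 genes the induced cells exceeded each of the other 4 groups, 18 of them at least 4-fold, and in 5 genes they lay below each. The following were chosen after their values were seen. They included Etv2, higher by 4.08 or more, Lrrc55 (3.81), Lrg1 (3.80), a secreted glycoprotein gene of vessels and liver, and Clec4e (3.34), a pattern receptor of myeloid cells. Signals of the other groups were dim for these genes, so the differences give no rank. Aplnr, the apelin receptor of growing vessels, was above each by 1.64 or more. Of 145 genes at least 2-fold higher than in skin fibroblasts in both lung endothelial cells and MS-1, 59 (40.7%) rose on conversion, against 24 of 231 (10.4%) higher in lung endothelial cells alone, 152 of 941 (16.2%) higher in MS-1 alone and 257 of 18621 (1.38%) of the rest. Whether these shares differ was not tested, and the calls behind them share the spread of each gene. Hoxa5 stood at 11.19 and 11.10 on the lung endothelial arrays and at 8.58, 8.43 and 8.51 on the induced ones.

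The 6 induced and mock-infected arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 655 genes and the highest other 9, with 1 split as large, the real one. For genes moving the same way as in the natural difference the values were 167 and 6 (1 split as large), for endothelial signature genes 59 and 1 (1 split), for fibroblast signature genes 23 and 2 (1 split), and for gene lists 11 and 12 (3 splits as large). Every other split mixed induced and mock-infected arrays within each group. Their differences then entered the spread, which keeps genes from passing, so the other splits are no baseline without an effect.

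On the array of induced replicate 1, 9 genes of the endothelial identity and transcription factor lists were at least 4-fold above both other induced arrays, among them Erg, an ETS factor of endothelium, at 11.01 against 7.14 and 7.25, and Pecam1; over all genes 42 were so far above, with Angpt2, Bmp4 and Mcam among them, against 9 and 17 on the arrays of replicates 2 and 3. The interferon list averaged 10.33 there and 8.761 and 8.896 on the others, and Hoxd10 stood at 10.63 against 8.06 and 7.72, both also high in MS-1 (10.79 and 10.71, and 11.70 and 11.63). The tables argue against MS-1 RNA as the whole cause: 59 genes abundant in MS-1 and outside the endothelial lists implied a median share of 5.22% (quartiles 1.85 and 14.5), and the 9 genes 40.3% (15.4 to 106), while the MS-1 gene Chil5 stood at 5.50 there and at 11.74 and 11.54 in MS-1. The 9 genes were picked for being high on this array and the 59 were not, so the larger share of the 9 follows in part from the choice. RNA like that on the lung endothelial arrays was tried in the same way, with the same limit. The 11 genes abundant there and outside those lists implied a median share of 4.51% (quartiles 0.155 and 39.3), and the lowest of the 9 genes 67%. Bmp4 gave 90.4%, Serpinb6b 68.1%, Smoc1 49% and Atp1b1 29.6%, but Map2 gave 0.158% and Tnfsf18 0.151%. This argues against RNA of that mixture as the whole cause. Those arrays may also carry RNA of other lung cells, and the 11 genes need not be endothelial. Lung endothelial RNA without the other cells can therefore not be excluded. A fuller conversion in that culture, an interferon response, or RNA of endothelial cells not measured here, may lie behind the pattern, and none of these was tested.

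On the lung endothelial arrays fibroblast genes reached a median of 58.1% of the skin fibroblast level (quartiles 28 and 74.7). The HoxC genes Hoxc8, Hoxc6 and Hoxc9, abundant in skin fibroblasts, reached a median of 7.99% (highest 12.9), which argues against skin fibroblast RNA. Of the 26 mesothelium, macrophage and leukocyte genes 13 rose against skin fibroblasts, which is consistent with RNA of other lung cells; Lrrn4, a mesothelial gene, stood at 11.23 and 8.55 in replicates 1 and 2, and C1qb, a complement gene of macrophages, at 8.35 and 10.38. Mesenchymal drift of the endothelial cells in culture cannot be told apart from lung fibroblasts or mesothelium, since 4 mesothelium genes rose as well. Whether the cells were sorted is not given in the sources used here.

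From the 78 genes above each other group, 12 known from myeloid cells, such as Clec4e, Csf2rb, a cytokine receptor subunit, and Cd14, were picked by hand after their values were seen, so that their size (median 2.46 over mock-infected fibroblasts, 1.36 to 3.83) follows from the choice; the fixed macrophage and leukocyte list was not called (camera adjusted p = 0.209). The 14 macrophage markers that were low in mock-infected fibroblasts had a median of -0.0224 (-0.231 to 0.777) and 0 rose in limma. Other markers, already present in mock-infected fibroblasts, went the other way without passing: Lyz2 differed by 1.82 (adjusted p = 0.104) and Cd53 by 1.36 (0.102), and 3 list members rose when adjusted over the list alone. Macrophages would also bring abundant transcripts such as Tyrobp, at 7.04, 7.07 and 7.23 in the induced cells and 7.72, 7.30 and 7.02 in the mock-infected ones, which argues against macrophage RNA as the whole source. An effect of the transferred blood and endothelial factors on these genes may remain, and was not tested.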
